A study of Mus musculus with 6 samples.

How the data were processed

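RNA was measured in regulatory T (Treg) cells from the colonic lamina propria, the connective layer under the gut epithelium, of male C57BL/6 mice. In mice whose Treg cells lack Rorc, a Cre recombinase expressed with a yellow fluorescent protein from Foxp3 removes a floxed Rorc segment in Foxp3-expressing cells. The comparison group carried the same Cre with intact Rorc. Per the labels' protocols, 1000 live cells positive for T cell receptor beta, CD4 and the Foxp3 reporter, and negative for Nrp1 and CD19, went into each library. The labels place 3 samples in each of the 2 genotypes. They do not say that the 3 are separate animals or sorts, so the p-values measure the spread between these samples, which may be partly technical.

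Per the labels' protocols, cDNA was primed with an oligo-dT primer carrying a T7 promoter and a random molecular identifier, amplified by in vitro transcription, fragmented, ligated and sequenced. The reads therefore come from near the 3′ ends of transcripts. Whether the molecular identifiers were collapsed is not given in the sources used here, nor is the strand setting of the counting. Per the submitters' processing notes, TopHat and TopHat2, Picard, SAMtools 0.1.19, HTSeq and DESeq were used and the genome build was mm10, with no role or order stated. The authors deposited 1 table of whole-number read counts per gene symbol and 1 table of normalized signal values. On inspection of the values, each column of the deposited normalized signal table was the matching count column divided by 1 factor per sample. The factors ran from 0.851 to 1.61.

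The count table holds 38406 gene rows, of which 12493 have no count in any library. All 37 genes of the mitochondrial genome are listed at 0 in each library, so mitochondrial share could not serve as a measure of RNA quality. Of the symbols, 27 had been turned into date-like text, and 2 of these stood on more than 1 row. Counts of genes summed to between 936271 and 2212333 per library. Counting error is covered by the 95% exact binomial intervals given with shares, and these intervals do not cover amplification.

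Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's expression filter (minimum count 10, minimum total count 15), which left 13802 genes, and libraries were scaled by trimmed mean of M values. A quasi-likelihood model with robust dispersion compared the genotypes over all 6 libraries, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are given on the log2 scale as Rorc-deleted minus wild-type with their standard errors (SE), and levels as CPM, the count scaled to the effective library total, as mean ± SD. With 3 samples against 3, an exact two-sided permutation test cannot give a p below 0.1, so single genes were tested by the model alone.

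Before the data were examined, 26 gene lists were fixed. They cover type 17, type 2 and type 1 T cell genes, Treg signature genes, suppressive molecules, thymic Treg markers, gut homing and trafficking, resting and conventional T cell markers, immediate early, heat shock, NF-kB target, interferon response, proliferation, cholesterol synthesis, clock, glycolysis, oxidative phosphorylation (OXPHOS), ribosomal protein and mitochondrial genome genes, and markers of B and plasma cells, myeloid cells, epithelium, stroma and endothelium, cytotoxic and innate lymphocytes, and red and mast cells. OXPHOS, ribosomal protein and mitochondrial genome lists were made from symbol patterns, and the ribosomal pattern also takes kinases such as Rps6ka3, the binding protein Rps19bp1 and Rps4y2, a transcribed pseudogene in the annotation used. Through an older symbol, 5 listed genes were matched, and 5 others were not matched to a row. For each list, members were also adjusted over the list alone. The 24 lists with at least 5 tested members were tested with camera of limma 3.58.1 on voom log2 CPM at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it.

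The rule for named genes, also fixed beforehand, took Rorc, Foxp3 and Nrp1, then up to 12 genes per direction past the adjusted threshold. Where fewer than 6 passed in a direction, it took the genes with the smallest p up to 6, named as not passing. Of each list it took up to 4 tested members with the smallest p and any member past the threshold. Provisional symbols and pseudogenes were left out of the ranking. Coordinates are 1-based on GRCm38, the same assembly as mm10, from GENCODE M21, which was matched by symbol and is not stated to be the annotation of the counting. Of the tested symbols, 12772 were found in it.

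The code was tested on simulated counts drawn from the means, depths and spread of these libraries. Over 12983 simulated genes, the model recovered 4.3% of genes changed by 2-fold, 23.9% at 4-fold, 74% at 8-fold and 95.9% at 16-fold, with 7 calls among 12791 unchanged genes. Each fold size was given to 46 to 50 of these genes, and genes of low mean level were left out of the draw. A shift of 1 log2 unit given to the cholesterol list was called by camera, with 0 other calls among the 24 lists. Each gene was drawn independently, without variation shared between genes, so this does not show how often real libraries give false list calls.

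Alternatives fixed beforehand were DESeq2 size factors, no filter on low counts, a filter of CPM 10 in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, leaving out each library in turn, the authors' normalized values with limma-trend after log2 of the value plus 1, and removal of ribosomal, mitochondrial and immunoglobulin genes. Chosen after seeing the data were a fit without the 2 libraries that stood apart, a covariate for background reads, and limma-voom with sample quality weights. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.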

Results

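The libraries profiled Nrp1-negative Treg cells of the mouse colon with and without Rorc, the gene for the transcription factor ROR gamma t, which directs type 17 T cell differentiation and is also found in a share of colonic Treg cells. Expression was measured in 3 Rorc-deleted and 3 wild-type libraries of 1000 sorted cells each. Total counts were 1862242, 1079338 and 1614815 in Rorc-deleted replicates 1, 2 and 3, and 936271, 2212333 and 1620350 in wild-type replicates 1, 2 and 3. At least 1 count was found for between 18475 and 22320 genes per library. The labels give ages of 13, 14 and 15 weeks for the Rorc-deleted mice and 10, 11 and 12 weeks for the wild-type mice, although the series describes littermates, so every genotype difference below is also a difference in the stated age.

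The targeted gene was lower in each library that carries the deletion. Rorc (chromosome 3, 94372794 to 94398276, plus strand) had 8, 6 and 6 counts in the Rorc-deleted libraries and 35, 162 and 67 in the wild-type libraries. This corresponds to 4.45 ± 0.73 against 53.7 ± 20.3 CPM (SD, n = 3 each), 12.0-fold more in wild-type cells. The log2 fold change was −3.59 (SE 0.53), with an adjusted p of 0.242 over all genes in edgeR's quasi-likelihood test and 0.000525 adjusted over the list alone. Which exons are floxed is not given in the sources used here, and a transcript that kept its 3′ end would still be counted, so the counts left in the deleted libraries do not measure how complete the deletion was. Foxp3 (chromosome X, 7573644 to 7595245), the transcription factor that defines Treg cells, was detected in each library, at 40.3 ± 26.8 CPM with the deletion and 33.0 ± 12.8 without, a log2 fold change of 0.28 (SE 0.60), and −0.23 to 0.84 over the alternatives. It was lowest in Rorc-deleted replicate 2 (13 counts, 11.3 CPM) and wild-type replicate 1 (19 counts, 19.4 CPM), against 34.8 to 64.1 CPM in the others. Nrp1 (chromosome 8, 128358604 to 128503363), whose protein was used to exclude cells in the sort, had 113, 101 and 63 counts in Rorc-deleted and 79, 114 and 324 in wild-type libraries. Its means, 63.0 ± 24.2 CPM with the deletion and 125 ± 101 without, were above those of Foxp3. The log2 fold change was −0.99 (SE 0.59). For the gene Nrp1 wild-type replicate 3 carried most of this difference, and without it the value was −0.09.

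Outside Rorc, the genes with the smallest p-values by the naming rule were the following, higher ones first. Ifng (chromosome 10, 118441046 to 118445892), the main type 1 cytokine, read 86.5 ± 19 against 10.9 ± 1.5 CPM, 7.82-fold more with the deletion (log2 fold change 2.97, SE 0.43, adjusted p = 0.242 over all genes). Il4 (chromosome 11, 53602982 to 53618669), a type 2 cytokine, read 98.4 ± 76.8 against 7.80 ± 4.82 CPM, 13.1-fold more (3.71, SE 0.74), or 2.94 on the log2 scale without Rorc-deleted replicate 3, its highest library. Wild-type counts were low for both cytokines, at 9, 25 and 16 for Ifng and 13, 9 and 8 for Il4, so both folds rest on small denominators. Epas1, the gene of the hypoxia-inducible factor HIF-2 alpha (chromosome 17, 86753700 to 86833410), read 4.96-fold more, Fastkd3, a mitochondrial RNA-binding protein (chromosome 13, 68582234 to 68592338), 4.50-fold, Ccl1, a chemokine (chromosome 11), 4.12-fold and Nkg7, a granule protein of cytotoxic lymphocytes (chromosome 7, 43437073 to 43438249), 3.2-fold. In the other direction, Ccr6, the receptor for the chemokine Ccl20 (chromosome 17, 8236043 to 8257141), read 35.4 ± 11.0 CPM in wild-type and 5.42 ± 1.37 in Rorc-deleted cells (log2 fold change −2.71, SE 0.56). Alkbh7 (chromosome 17, 56997339 to 56999322), Mir5105, C2cd4b (chromosome 9, 67759437 to 67760930) and the linker histone gene Hist1h1d (chromosome 13, 23553262 to 23560686) followed, with log2 fold changes of −3.39 (SE 0.84), −3.21 (SE 0.76), −2.29 (SE 0.57) and −2.03 (SE 0.52). Single wild-type libraries carried much of the first 2 differences. The gene Alkbh7 had 245 counts in wild-type replicate 3 against 61 and 24 in the others, and its log2 fold change was −2.12 without that library and −1.41 with sample quality weights. Mir5105 had 501 counts in wild-type replicate 2 against 30 and 64, and stood at −1.76 without it. For Rorc and for each of these 11 genes, the 3 libraries of one genotype lay on one side of the 3 of the other.

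**Figure D1:**
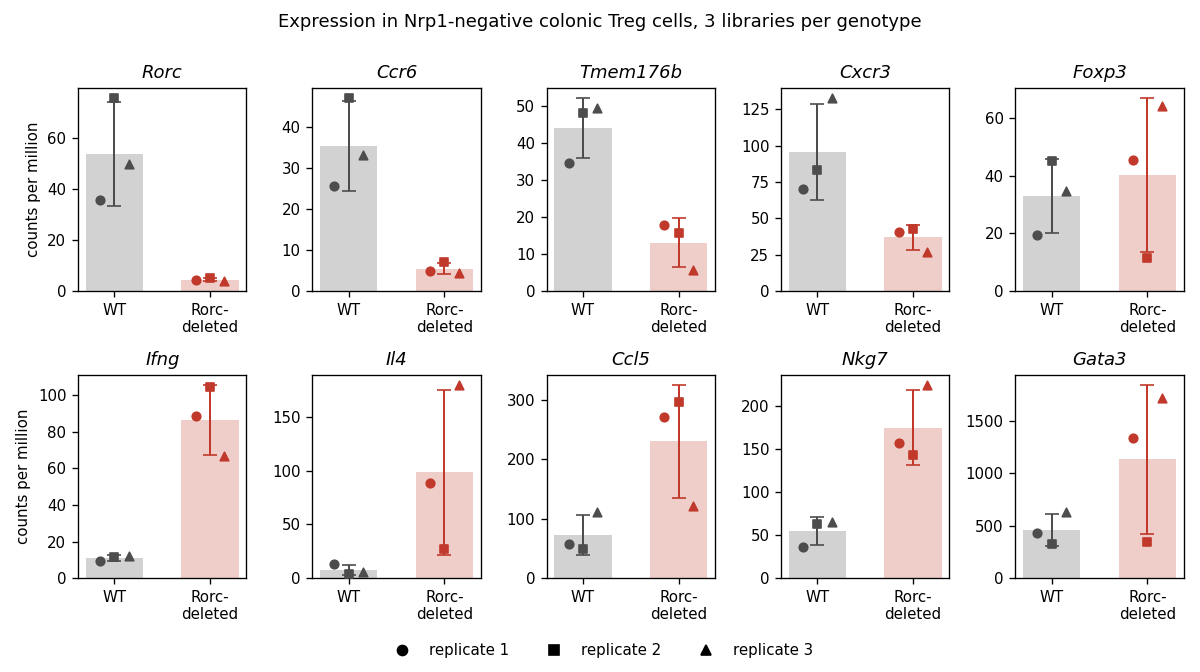
Bars show the mean CPM, error bars the SD and points the 3 libraries of each genotype, for 10 named genes on linear axes that start at 0. Rorc falls from a mean of 53.7 to 4.45 CPM and Ifng stands at 10.9 against 86.5 CPM with no overlap of libraries, while Foxp3 and Gata3 overlap.

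None of these genes passed the threshold over all genes. The edgeR test called 0 of 13802 genes, with 251 at an unadjusted p under 0.05 against about 690 that chance alone would give, DESeq2 called 8 and limma-voom 0. Non-overlapping libraries were seen for 856 genes, or 6.2%, where chance gives 10%. Variation between libraries of one genotype was large, with a biological coefficient of variation of 0.509 and correlations of log2 CPM across genes of 0.70 to 0.91 within a genotype and 0.60 to 0.91 between genotypes. The largest component of variation, 61.6% of the variance, set Rorc-deleted replicate 2 and wild-type replicate 1 apart from the other 4 libraries. Those 2 also had the highest shares of counts in olfactory and vomeronasal receptor genes, which T cells are not known to use, at 0.374% (95% exact binomial interval 0.362% to 0.385%) and 0.277% (0.267% to 0.288%), against 0.083% to 0.159% in the others. The same 2 had the lowest Foxp3 and the lowest mean of Treg signature genes (6.93 and 7.175 log2 CPM, against 7.855 to 8.242 in the others). Their means of cytotoxic and of stromal markers were the highest. What this reflects was not tested. Without both libraries, a fit chosen after seeing the data, edgeR called 12 genes, 9 higher and 3 lower with the deletion. Il4, Epas1 and Ifng were among the higher genes, and Rorc and Ccr6 among the lower. Leaving out wild-type replicate 1 alone also gave 12 genes, and leaving out Rorc-deleted replicate 2 alone gave 2. The share of genes at an unadjusted p under 0.05 was 1.8% in the main fit. It rose to 19.4% without wild-type replicate 1, 13.5% without both libraries and 15.6% with sample quality weights. In the other settings it was 0.8% to 4.1%. The shortfall against chance in the main fit was therefore not seen in every setting.

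**Figure D2:**
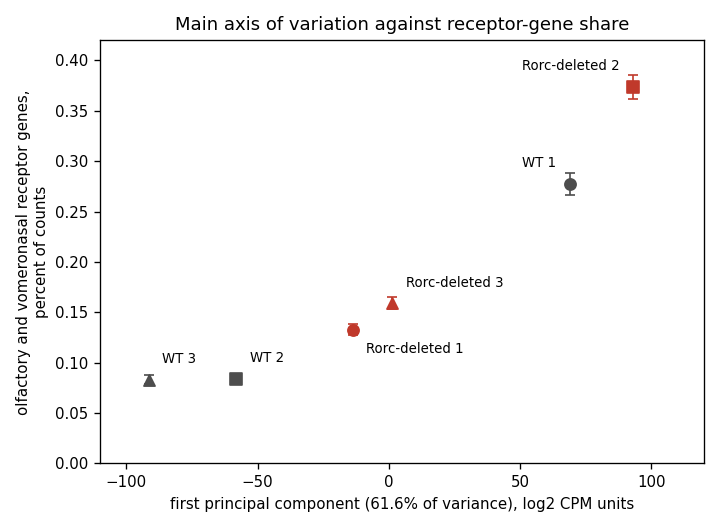
Each point is 1 library, with its position on the first principal component of log2 CPM on the x axis and the percent of its counts in olfactory and vomeronasal receptor genes on the y axis. Error bars are 95% exact binomial intervals. Rorc-deleted replicate 2 at 0.374% and wild-type replicate 1 at 0.277% lie to the right of the other 4 libraries, and each genotype has libraries on both sides.

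Of the type 17 genes, 3 of the 15 tested members fell and 0 rose, adjusted over the list alone, while 0 passed over all genes. The 3 were Rorc, Ccr6 (adjusted p = 0.00415) and Tmem176b, a membrane protein gene found with Rorc in type 17 cells (chromosome 6, 48833818 to 48841496, log2 fold change −1.75, SE 0.53, adjusted p = 0.0361). Tmem176b overlaps Tmem176a on the other strand, so reads from the shared stretch cannot be told apart where the counting ignores strand. Whether that stretch reaches the 3′ ends, where the reads lie, was not examined. Rorc, Foxp3 and Il12rb2 also overlap genes on the other strand. Il23r, the receptor for the cytokine interleukin-23, read 25.1 ± 21.3 against 58.2 ± 26.9 CPM and did not pass (−1.24, SE 0.62). The list holds Rorc, so 1 of the 3 falls and part of the list's shift come from the targeted gene itself. The list was not tested without Rorc. Its median log2 fold change was −0.39 and camera called it lower (adjusted p = 0.00649), a call that was lost with an estimated correlation (adjusted p = 0.579), with fry (0.562) and with the background share as a covariate (0.0875). Without wild-type replicate 2 the median was 0.06 with 8 of 16 members positive, while the mean was −0.36 and the camera call remained (0.0441). Without both libraries that stood apart, 5 members fell and 2 rose. Among the 5 was Il23r (−2.26, SE 0.50). Without wild-type replicate 1 alone, 4 members fell and 1 rose, and 2 fell without Rorc-deleted replicate 3, wild-type replicate 2 or wild-type replicate 3, or with the replicate block.

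Among the 18 tested genes of gut homing and trafficking, 15 had negative fold changes and 1, Ccr6, fell when adjusted over the list alone (adjusted p = 0.00996). Cxcr3, a chemokine receptor of type 1 cells, read 36.8 ± 8.5 against 95.7 ± 33.1 CPM (−1.38, SE 0.43), Ccr2 −0.90 (SE 0.63) and S1pr1, the receptor for T cell exit from tissue, −0.81 (SE 0.59). Camera called the list lower (adjusted p = 0.00549) at a median of −0.45, but not with an estimated correlation (adjusted p = 0.665). The camera call ended without wild-type replicate 2 (adjusted p = 0.0623) and with the background covariate (0.506, median −0.06, 8 of 18 positive), and the Ccr6 call over the list ended without that library or without Rorc-deleted replicate 3, while 2 members fell without wild-type replicate 1.

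Of 12 type 2 genes, Il4 rose when adjusted over the list alone (adjusted p = 0.00547) and 0 fell. Areg, an epidermal growth factor family ligand linked to tissue repair, read 473 ± 274 against 189 ± 43.0 CPM (log2 fold change 1.33, SE 0.51), Gata3, the type 2 transcription factor, 1133 ± 710 against 459 ± 155 CPM (1.30, SE 0.60) and Il1rl1, the receptor for interleukin-33, 272 ± 130 against 130 ± 28.4 CPM (1.07, SE 0.49). These 3 did not pass over the list (adjusted p = 0.156 for each). Gata3 reached 1340 and 1717 CPM in Rorc-deleted replicates 1 and 3, and 343 CPM in replicate 2, inside the wild-type range of 321 to 627. Without Rorc-deleted replicate 2, 5 type 2 genes passed over the list, and without both libraries that stood apart also 5, among the latter Areg, Gata3 and Il1rl1. Without any 1 wild-type library, 2 passed. Camera did not call the list in the fit of genotype alone (adjusted p = 0.0974, and 0.721 with an estimated correlation). The list was called higher with the replicate block (0.0498), the background covariate (2.97e-05) or quality weights (0.033), without both libraries that stood apart (0.00458), and without Rorc-deleted replicate 2 (5.53e-08) or wild-type replicate 3 (0.00236).

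Type 1 genes moved both ways. Adjusted over the list alone, 3 of 16 rose and 1 fell. Ifng rose (adjusted p = 0.00051), as did Ccl5, a chemokine of effector T cells (230 ± 95.4 against 73.2 ± 33.6 CPM, 1.65, SE 0.51), and Il12rb2, a chain of the interleukin-12 receptor (1.26, SE 0.41), while Cxcr3 fell, each of these 3 at an adjusted p of 0.0452. Camera did not call the list (adjusted p = 0.357). The count on the list varied. Without any 1 Rorc-deleted library or wild-type replicate 2, 1 member rose and 0 fell, and 2 rose without wild-type replicate 3. Without wild-type replicate 1, 1 rose and 2 fell, and without both libraries that stood apart 1 rose and 1 fell. With the replicate block, no filter or the authors' normalized values, 1 rose. With DESeq2, limma-voom or the background covariate 4 rose and 2 fell, and with quality weights 3 rose and 2 fell. Over all 466 listed genes, 2 passed, Ifng and Rorc (adjusted p = 0.00816 for both).

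Markers of conventional, Foxp3-negative T cells were the list with the clearest rise. Ifng, Il4 and Themis, a T cell receptor signalling protein (175 ± 37.6 against 69.8 ± 26.8 CPM, 1.33, SE 0.44), rose among 7 tested members when adjusted over the list alone, and 0 fell. Il21, a cytokine of follicular and type 17 cells, did not pass (0.99, SE 1.06). The remaining members, Thy1 (−0.28, SE 0.50), Cd40lg (0.57, SE 1.39) and Bcl6 (0.06, SE 0.48), did not pass either. Camera called the list higher (adjusted p = 5.01e-05) and so did fry (adjusted p = 0.0381). Camera run with an estimated correlation did not call it (adjusted p = 0.2). The estimate was −0.14, below the preset of 0.01, so correlation between members does not account for the lost call. The count of members that rose went from 3 to 2 without Rorc-deleted replicate 1 or 3 or wild-type replicate 3, and with the replicate block. Ifng and Il4 also stand on the type 1 and type 2 lists, so these lists are not independent. Of the 7 tested cytotoxic and innate lymphocyte markers, Nkg7 rose over the list alone (adjusted p = 0.0188), while Gzma (12.1 against 7.34 CPM), Klrk1 (13.0 against 8.46 CPM) and Cd8b1 (6.98 against 15.9 CPM) were near the detection limit. Camera called this list higher (adjusted p = 0.0358) and not with an estimated correlation (adjusted p = 0.665). The Nkg7 call over the list held with Rorc-deleted replicate 2 left out. It ended with any other single library left out, with the replicate block or without a filter on low counts. The camera call ended without Rorc-deleted replicate 1 or 2 or wild-type replicate 1 or 2, with the replicate block (0.112), with the background covariate (0.28), with the authors' normalized values (0.0874) and without a filter on low counts (0.153).

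**Figure D3:**
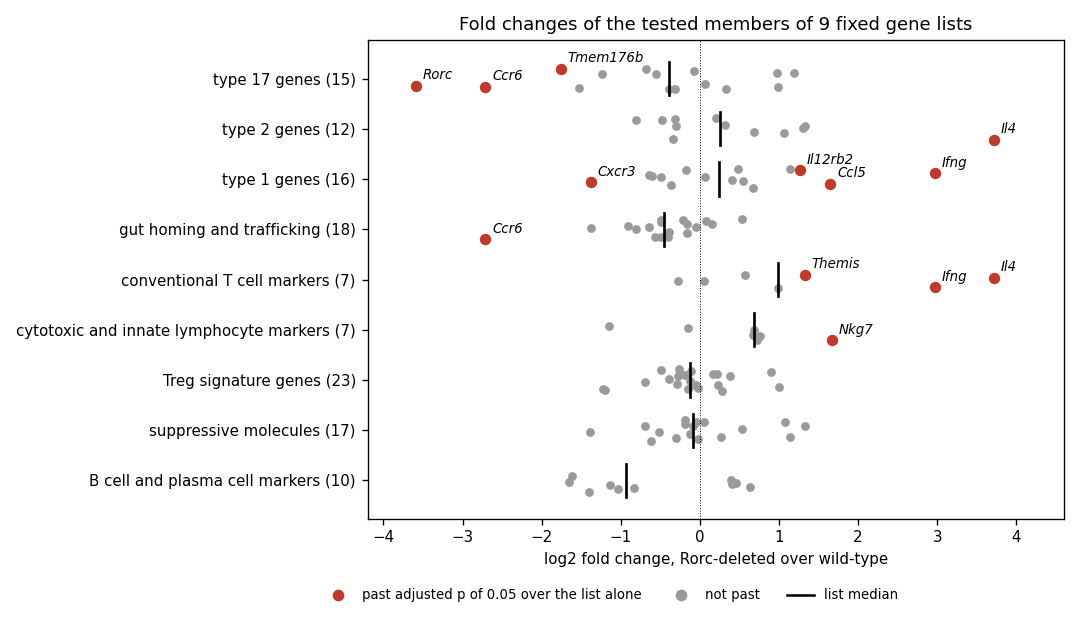
Each point is a tested member of 1 of 9 fixed lists, placed by its log2 fold change of Rorc-deleted over wild-type cells, with the number of members in brackets. Red points passed an adjusted p of 0.05 over their list alone and black lines mark list medians. Rorc at −3.59, Ccr6 at −2.71, Ifng at 2.97 and Il4 at 3.71 lie farthest out, while Treg signature genes centre near 0 with a median of −0.13.

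The Treg programme gave no call in the fit of genotype alone. Of 23 tested Treg signature genes, 0 passed over the list alone and the median log2 fold change was −0.13. The members with the smallest p were Cd81 (−1.19, SE 0.58), Klrg1, a marker of terminally differentiated cells (1.00, SE 0.63), Tnfrsf9 (0.90, SE 0.58) and Lrrc32 (−1.22, SE 0.85). Suppressive molecules also gave 0 calls among 17, with Havcr2, the gene of Tim-3, at 61.2 ± 21.8 against 161 ± 86.8 CPM (−1.39, SE 0.50), Gzmb, granzyme B, at 1016 ± 129 against 460 ± 238 CPM (1.14, SE 0.48) and Pdcd1, the gene of PD-1, at 1.07 (SE 0.67). Their median (−0.09) and mean (0.01) differed in sign. Thymic Treg markers, with Itgb8 (−0.71, SE 0.41), Ikzf2 (−0.29, SE 0.45) and Ikzf4 (−0.25, SE 0.51), gave 0 calls among 6, and resting T cell markers, with Sell (−1.70, SE 0.95), Tcf7 (−1.08, SE 0.68) and Satb1 (0.53, SE 0.42), 0 among 11, or 1 lower without wild-type replicate 1. The direction turned without wild-type replicate 3 for Lrrc32 (0.09) and Sell (0.30), and in at least 1 alternative for Ikzf2 and Ikzf4. Among suppressive molecules, Areg rose over the list without both libraries that stood apart, and 1 member rose and 1 fell with quality weights. Camera called none of these 4 lists, with adjusted p from 0.17 for the thymic markers to 0.765 for the suppressive molecules. Treg signature genes were called lower when Rorc-deleted replicate 1 or 3 or wild-type replicate 1 was left out (adjusted p = 0.0462, 0.0132 and 0.0257), and with the background covariate they and the suppressive molecules were called higher (0.000651 and 0.0493). For single genes tested over all genes, 4.3% of simulated 2-fold changes were recovered, so most such changes of single genes would be missed.

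In the fit of genotype alone, no single gene of the activation, stress and metabolism lists passed over its list, while with the background covariate 5 immediate early genes and 1 clock gene rose over theirs. Immediate early genes had 15 of 20 positive fold changes, with Fosl2, an AP-1 subunit, at 316 ± 100 against 146 ± 20.3 CPM (1.11, SE 0.43), Nr4a1 at 0.89 (SE 0.54), Dusp2 at 0.64 (SE 0.52) and Fosb at 0.58 (SE 0.52). NF-kB targets had 11 of 14 positive, with Ccl20 at 1.19 (SE 0.69), Nfkb1 at 0.80 (SE 0.56) and Birc3 at 0.70 (SE 0.50). Neither list was called by camera in the fit of genotype alone (adjusted p = 0.157 and 0.0586, and 0.771 and 0.721 with an estimated correlation). At the preset correlation both were called higher with the background covariate (2.96e-11 and 1.9e-10), without both libraries that stood apart (0.013 and 0.000623), and without Rorc-deleted replicate 2 (3.15e-07 and 6.81e-09) or wild-type replicate 3 (0.00483 and 0.00167). NF-kB targets were also called with quality weights (0.0185) and once ribosomal, mitochondrial and immunoglobulin genes were removed (0.0486). Proliferation genes such as Mcm3 (−0.71, SE 0.50), Cdk1 (−0.85, SE 0.60), Mcm6 (−0.56, SE 0.40) and Tubb5 (−0.63, SE 0.56), cholesterol synthesis genes such as Mvd (−0.79, SE 0.49), Sc4mol (−0.54, SE 0.40), Sc5d (−0.59, SE 0.49) and Insig1 (0.61, SE 0.50), clock genes such as Nr1d1 (−1.45, SE 0.70), Dbp (−0.86, SE 0.51), Bhlhe40 (0.82, SE 0.56) and Per1 (0.56, SE 0.58), and glycolysis genes such as Eno1 (−0.86, SE 0.47), Aldoa (−0.56, SE 0.57), Ldha (−0.42, SE 0.52) and Gapdh (−0.34, SE 0.45) were not called either, with adjusted p from 0.174 to 0.929. Proliferation and glycolysis genes were called lower without wild-type replicate 1 (0.0128 and 0.0494), and cholesterol genes without Rorc-deleted replicate 3 (0.0384). Proliferation genes were also called lower without both libraries that stood apart (0.00458), while without wild-type replicate 3 the median turned to 0.19 with 20 of 27 positive. The fold changes of Dusp2, Tubb5, Per1, Aldoa, Ldha and Gapdh turned sign in at least 1 alternative.

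Camera called 4 further lists lower with the deletion, and an estimated correlation ended each call. Ribosomal protein genes had 86 of 93 negative fold changes (median −0.33, adjusted p = 5.01e-05, and 0.721 with an estimated correlation), with Rps7 at −0.68 (SE 0.48), Rps4y2 at −1.49 (SE 0.56), Rps19bp1 at −1.04 (SE 0.65) and Rps6ka3 at −0.58 (SE 0.40). OXPHOS genes had 76 of 82 negative (median −0.35, adjusted p = 5.01e-05, and 0.721 with an estimated correlation), led by the complex I subunits Ndufc2 (−1.38, SE 0.59), Ndufs8 (−0.92, SE 0.50), Ndufb6 (−0.83, SE 0.46) and Ndufa8 (−0.87, SE 0.50). Heat shock genes had 11 of 12 negative (median −0.24, adjusted p = 0.0201, and 0.721 with an estimated correlation), with Hspe1 at −0.70 (SE 0.54), Hspb1 at −0.79 (SE 0.69), Hsp90aa1 at −0.44 (SE 0.49) and Hspa5, which turned sign in 1 alternative, at 0.33 (SE 0.49). Interferon response genes had 14 of 19 negative (median −0.33, adjusted p = 0.0359, and 0.665 with an estimated correlation), with Ifi27l2a at −0.84 (SE 0.54), Isg20 at −0.71 (SE 0.51), Stat1 at −0.60 (SE 0.44) and Ifi35 at −0.65 (SE 0.48). Ribosomal protein genes took 16.4% of counts in wild-type replicate 3 and 8.58% to 12.2% in the others, and without that library the adjusted p was 0.541 for OXPHOS and 0.987 for ribosomal genes, the latter with the direction turned. The ribosomal call also ended without Rorc-deleted replicate 2 (0.0808), the heat shock call without Rorc-deleted replicate 2 (0.893, direction turned) or wild-type replicate 2 or 3 (0.0673 and 0.0654), and the interferon call without Rorc-deleted replicate 2 or 3 (0.0645 and 0.235) or wild-type replicate 2 or 3 (0.0673 and 0.0721) or with the replicate block (0.0557). With the background covariate none of the 4 was called (0.617 for ribosomal, 0.991 for OXPHOS, 0.853 for heat shock and 0.562 for interferon genes).

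Markers of other cell types were detected. Of the 10 tested B and plasma cell genes, 6 had negative and 4 positive fold changes. The immunoglobulin genes read lower with the deletion, with Igha at 17.6 ± 3.0 against 55.5 ± 26.8 CPM (−1.65, SE 0.50), Igj at −1.62 (SE 0.58) and Ighm at 106 ± 52.7 against 281 ± 127 CPM (−1.41, SE 0.52), as did Cd79b, a chain of the B cell receptor, at −1.14 (SE 0.54). Adjusted over the list alone, 0 passed (adjusted p = 0.072 for Igha, Igj and Ighm), while 4 fell without both libraries that stood apart, 4 fell and 3 rose without wild-type replicate 1, 5 fell and 1 rose with quality weights, 3 fell with DESeq2 and 2 without a filter. Camera called the list lower (adjusted p = 0.0464, and 0.579 with an estimated correlation, which was −0.06 and so below the preset). The call ended without Rorc-deleted replicate 1 or 3 (0.0959 and 0.235) or wild-type replicate 1 or 2 (0.181 and 0.0673), and with the filter of CPM 10 in 3 libraries (0.108). With immunoglobulin genes removed the camera call was lost (adjusted p = 0.659) and the direction was mixed, with 4 of 6 positive, a median of 0.40 and a mean of −0.01. Epithelial markers read higher, with the goblet cell genes Spink4 at 37.3 ± 30.9 against 9.21 ± 6.89 CPM (2.05, SE 0.86) and Muc2 at 1.28 (SE 0.77), and the keratins Krt8 at 1.95 (SE 0.94) and Krt18 at 1.27 (SE 0.97). With 0 of 12 members past the list threshold, or 2 higher without a filter and 1 with quality weights, camera called this list higher (adjusted p = 0.0138, and 0.665 with an estimated correlation). Krt8 had 199 counts in Rorc-deleted replicate 3 and 11 to 24 in the other 5 libraries, and the list's call ended without that library (0.235), where the fold change of Krt8 was −0.03, or wild-type replicate 1 or 2 (0.0575 and 0.385) or with the background covariate (0.136). Myeloid markers gave 0 calls among 6 (Cd74 −1.22, SE 0.49, Ctss −1.02, SE 0.45, Emr1 1.47, SE 0.83, and Cst3 −0.62, SE 0.48) and a camera adjusted p of 0.14. Without wild-type replicate 1, without both libraries or with quality weights, 2 fell and 1 rose over the list. Stromal and endothelial markers gave 0 among 11 (Dcn 1.93, SE 0.82, Col3a1 1.54, SE 0.66, Sparc −1.73, SE 0.83, and Cdh5 1.45, SE 1.01) and 0.119, or 0.0109 without wild-type replicate 3 and 0.033 with quality weights. A single stromal gene rose without wild-type replicate 1, and 1 fell without wild-type replicate 2 or without a filter. Sparc turned to 0.20 with quality weights. Of the red and mast cell markers, 2 were tested, Kit (1.32, SE 0.59) and Cpa3 (1.51, SE 0.93), with 0 calls, or 1 higher in 5 of the alternatives. Mitochondrial genome genes were listed at 0 in each library and not tested.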

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

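Rorc read lower with the deletion under all 17 alternatives. It stayed above the threshold over all genes in 11 of them and passed without a filter on low counts (log2 fold change −3.64), with the DESeq2 Wald test (−3.58), without both libraries that stood apart (−3.89), with the background share as a covariate (−3.37) and with sample quality weights (−3.84). Leaving out 1 library at a time gave −3.86 to −3.23, and it passed without wild-type replicate 1. The count of called genes, 0 in the report, was 17 without a filter, 8 with DESeq2, 12 without both libraries, 3 with the covariate and 6 with quality weights. It was 0 to 12 with 1 library left out, and 0 in the other settings. Ifng, Il4 and Rorc were each called in 6 of 18 settings, the main one included, and kept their direction in all. The count of called lists, 10 in the report, was 0 with an estimated correlation, 1 with fry and 4 to 10 with 1 library left out, the 4 without wild-type replicate 2. Some lists changed direction. With the background covariate the adjusted p was 0.000651 for Treg signature genes and 0.0493 for suppressive molecules, both then higher, and 0.853 for heat shock genes. For B cell markers it was 0.659 once immunoglobulin genes were removed, where their direction was mixed (median log2 fold change 0.40, mean −0.01). With 1 library left out the adjusted p ran from 1.04e-08 to 0.893 for heat shock genes and from 1.69e-07 to 0.987 for ribosomal protein genes. Without a filter the B cell, epithelial and cytotoxic lists were not called (0.0956, 0.0523 and 0.153). With quality weights the heat shock, ribosomal and B cell lists were not called (0.106, 0.0752 and 0.0577), and without both libraries the heat shock and B cell lists (0.343 and 0.123). Apart from the removal of listed genes, the cause was not tested.

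The series describes wild-type littermates as paired, but the labels do not tie equal replicate numbers to a litter, and the stated ages of equal numbers differ. Deviations from the group means correlated at −0.54, −0.44 and 0.29 for replicates 1, 2 and 3 across genotypes. Wild-type replicate 1 and Rorc-deleted replicate 2, which stood apart, are in the first 2 of these pairs. The correlations were not recomputed without them, so whether the numbers mark litters or batches stays open. With the replicate block, 0 genes and 9 lists were called. The cytotoxic (0.112) and interferon (0.0557) lists lost their calls and type 2 genes gained one (0.0498). Recovery in simulation was 74% for 8-fold and 4.3% for 2-fold changes, so tests of single genes over all genes reach mainly large changes. The simulation drew each gene independently, without the shared variation that set 2 libraries apart. It also changed 46 to 50 genes at each fold size, none of low level. So many large changes make the adjusted threshold easier to pass than few would. In the real data Rorc at 12.0-fold and Il4 at 13.1-fold did not pass, so true recovery may be lower.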

Other observations

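Several genes outside the naming rule passed the threshold over all genes in 1 or more of the 18 settings, and those named here were chosen after their values were seen. Il13, a type 2 cytokine whose gene lies near Il4, had 20, 5 and 136 counts in Rorc-deleted and 3, 1 and 1 in wild-type libraries, too few for the main filter. Calca, the gene of the neuropeptide CGRP, had 85, 6 and 205 counts against 2, 6 and 10 and was called in 3 settings. Ramp1, which encodes a subunit of the CGRP receptor, went the other way with 22, 30 and 22 counts against 28, 141 and 172 (log2 fold change −2.11, SE 0.59 over 6 libraries, and −2.85, SE 0.46 without both libraries that stood apart). Il1r2, the decoy receptor for interleukin-1, had 61, 50 and 65 counts against 41, 286 and 348 (−1.89, SE 0.59). Among higher genes, the noncoding transcript 1700061F12Rik was called in 5 settings (139, 23 and 92 counts against 6, 12 and 12), Slco2b1, an organic anion transporter, in 3 (126, 48 and 92 against 37, 9 and 5), and Pxdc1 in 2 (211, 15 and 242 against 24, 35 and 12).

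Of the tests that follow, those of genotype and of the effector genes without 2 libraries were chosen only after the result was seen. Rorc-deleted replicate 2 and wild-type replicate 1 stood apart on the first principal component. Genotype does not set the 2 apart, since 1 of them is wild-type, which was known when that test was chosen. The component still ordered the genotypes among the other 4, at 1.27 and −13.72 in Rorc-deleted and −58.1 and −91.36 in wild-type libraries. Within the 2, the Rorc-deleted library lay at 93.09 and the wild-type one at 68.83. A part for genotype in this component is therefore not excluded. Depth alone is argued against. Over 20 thinnings of each library to 936271 counts, the gap stayed at 0.3455 of the range or more, against 0.3663 unthinned. Background reads from genes that T cells do not use remain a candidate explanation, because the lower of the 2 shares of receptor-gene counts was 1.744 times the highest share of the other 4. What produced such reads, for example low input of intact RNA, was not tested.

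Ifng, Il4, Ccl1, Ccl5 and Nkg7 read higher in Rorc-deleted cells. Without the 2 libraries that stood apart, the median log2 fold change of the 5 genes was 2.106. Background reads in those 2 libraries alone were set to bring it below 1, so the difference does not rest on these libraries. Each of the 5 genes already separated the genotypes with them included, so this outcome was likely. The libraries kept also differ in receptor-gene share, at 0.133% and 0.159% in Rorc-deleted and 0.0842% and 0.0830% in wild-type libraries. Background reads in general are therefore not excluded. Cytotoxic or innate lymphocytes that passed the gate for CD4 and T cell receptor beta stay open, because the 6 other markers of that list differed by 0.319 log2 CPM (SE 0.57), with an upper bound of 1.46 that does not exclude the value of 1 set beforehand, and Gzma and Klrk1, at 12.1 and 13.0 CPM, are too low to decide. Foxp3-negative CD4 T cells, which the reporter gate would remove, stay open too, with a difference of 0.948 log2 CPM (SE 0.39) over 5 other markers. Of these, Treg cells also express Thy1 and another list holds Il21. Both differences are means of log2 CPM, not fitted fold changes. A change in Treg cells that lack Rorc is a hypothesis that may account for the pattern, and so may the difference in stated age, which was not tested.

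Splitting the 6 libraries into 3 and 3 can be done in 10 ways, too few for a share under 0.05. For genes, the real split gave 0 calls and the highest other split 0, so 10 of 10 splits gave as many. No split can give fewer than 0, so this comparison cannot decide anything for genes. For lists, the real split gave 10 calls and the highest other split 15, and 4 of 10 splits gave as many. The split with 15 set Rorc-deleted replicates 1 and 3 and wild-type replicate 3 against the rest, so groupings other than genotype can also yield list calls at the preset correlation.

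All animals are labelled male, and Ddx3y of the Y chromosome read 77.8 to 192 CPM in each library, while Xist, which is expressed from the inactive X chromosome of females, read 72.2 CPM in wild-type replicate 3 and 3.62 to 34.2 CPM in the others. For these 2 genes CPM is the count scaled to the raw library total, not the effective total used elsewhere. Cells of a female or a mixed library cannot be ruled out for that replicate, and the OXPHOS and ribosomal calls ended without it (adjusted p = 0.541 and 0.987). The single annotated gene AC131780.1 took 0.265% to 2.06% of counts per library, and RP23-81C12.3 took 0.200% to 0.582% in Rorc-deleted and 0.776% to 1.69% in wild-type libraries.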
